A study of Mus musculus with 6 samples.

How the data were processed

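RNA of 6 P19 samples was sequenced, 3 after transfection with a negative control (NC) siRNA and 3 after transfection with an siRNA against Baf45d, all harvested on day 5 of retinoic acid. Libraries were made with an Illumina kit that the labels name without stating strand. The enrichment of the RNA, the aligner, the read counter and its use of strand are not given in the sources used here. Counts of genes that overlap an antisense gene, or that share sequence with pseudogenes, are therefore uncertain.

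The authors deposited 1 table of 54532 Ensembl genes, holding a raw count per gene and library per the file headers. The whole numbers summed to different totals, from 17127876 to 21224822 per library. The deposited FPKM values equalled counts divided by gene length and by a depth proportional to the DESeq2 size factor of each library, which was tested on the values. The authors' group columns are a signal, the mean of size-factor normalized counts per group. The authors' log2 fold changes, p-values and adjusted p-values came with the same table, and the submitters' processing notes name DESeq2 1.16.1. These notes name the build mm9, whereas 98.3% of the 54409 genes with an identifier in GENCODE M21 had the identical start and end there, so coordinates are given as GRCm38. The authors also deposited tables of KEGG and Reactome terms with a p-value, an adjusted p-value and counts of genes up and down per term, and a table of protein pairs with a score from 400 to 999 for each of 455 pairs.

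The main comparison was made on the counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by the default settings of filterByExpr, which left 16078 genes. Libraries were scaled by TMM. The quasi-likelihood F test with robust estimation, two-sided and fitted on group alone, gave log2 fold changes, standard errors (SE) and p-values, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, counts scaled to a common library size with TMM factors, as mean ± SD over 3 libraries.

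For gene groups, 24 lists with 586 distinct members were fixed before the data were examined. They cover pluripotency, neural progenitor, neuron, glia, neural crest, mesoderm, muscle, endothelium and blood, endoderm, mesenchyme and extracellular matrix, retinoic acid response, Hox, SMAD pathway components, SMAD target genes, Notch, Wnt, BAF complex subunits, cell cycle, interferon response, p53 response, integrated stress response, glycolysis and hypoxia, cholesterol synthesis and housekeeping. Each list was tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. A list score is the mean over members of log2 CPM minus the gene's mean over the 6 libraries, compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1. Named genes were chosen by a rule written before the data were examined: Dpf2, up to 10 genes each way past the threshold (none were), the 5 smallest p with a descriptive symbol, up to 4 members of each list past the threshold or otherwise the 2 with the smallest p, and Pax6, Pou5f1, Sox2, Nes, Smad1 to Smad5 and Tubb3. Other genes named below were chosen after their values were seen.

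The labels call the samples of a group biological replicates and number them 1 to 3 in both groups, without stating a shared batch. Deviations from the group means correlated over 16078 genes with r = 0.17, 0.13 and 0.35 for same-numbered libraries and with r from -0.24 to 0.12 for the other pairs, and each library correlated best with its own number. The numbers were therefore taken to pair the samples, on the strength of the data and not of the labels, and a fit with the replicate number as a block was run as an alternative. Libraries of 1 group differed by more than sampling noise, with chi-square per degree of freedom from 3.33 to 22.8, so none is a copy of another and all 6 were kept.

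The procedure was tested on simulated counts for the same design, with the dispersions and library sizes of the data. Without a block, 48.5% of 66 genes changed 1.5-fold were recovered, 70.3% of 64 changed 2-fold and 90.8% of 65 changed 3-fold, over 15833 simulated genes, and 4.23% of the calls were false. With the block the false share was 10.8%, above the nominal level. These counts held no shifts shared by libraries of the same number. With no gene changed, 4.82% of simulated genes had an unadjusted p under 0.05 without a block. The share was 1.84% when such shifts (SD 0.15 log2) were added. The data gave 2.85%, so the recovery rates and false shares need not hold for the data. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, stricter thresholds and each library left out in turn. Figures were drawn with matplotlib.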

Results

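The series asks what BAF45D does during early neural differentiation and how it relates to SMAD signaling. P19 is a mouse embryonal carcinoma cell line that forms neural cells when treated with retinoic acid. BAF45D, encoded by Dpf2, is a subunit of the BAF chromatin-remodelling complex. RNA was sequenced from 3 replicates given NC siRNA and 3 given Baf45d siRNA, all on day 5 of retinoic acid. Counts totalled 17767104, 21224822 and 17819591 in NC replicates 1 to 3 and 17560717, 17127876 and 18499169 in Baf45d replicates 1 to 3. At this depth and replication the median SE of a log2 fold change was 0.112 for genes at 5 CPM or more.

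Dpf2, the target of the siRNA (chromosome 19, 5896516 to 5913010, minus strand, GRCm38), was measured at nearly the same level in both groups. It stood at 156.1, 154.1 and 157.5 CPM in the NC libraries and at 148.2, 141.4 and 147.2 CPM in the Baf45d libraries. Group means were 155.9 ± 1.75 and 145.6 ± 3.68 CPM (SD, n = 3). The log2 fold change was -0.10 (SE 0.07, adjusted p = 0.996 in the edgeR quasi-likelihood test), a change of -6.59% with a 95% interval from -16.1% to 3.98%. Each Baf45d library lay below each NC library, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allow. The lowest library held 89.8% of the CPM of the highest. The transcript therefore gives no check of which libraries received the siRNA, and the groups below are named as the labels name them.

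**Figure D1:**
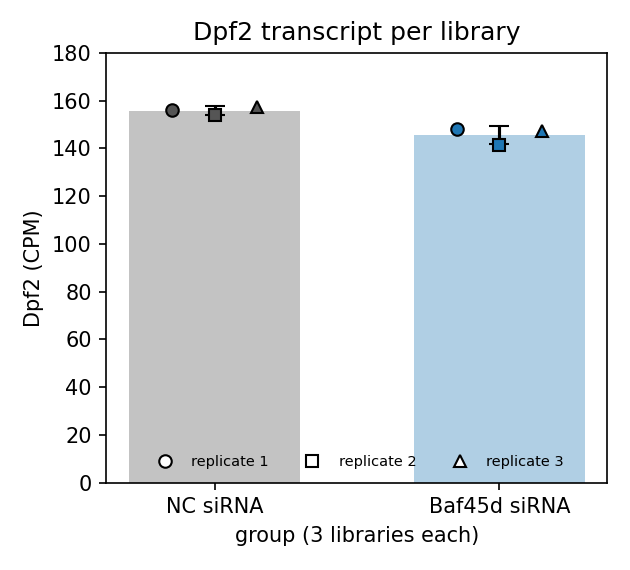
Dpf2 transcript (vertical axis, CPM) in the NC siRNA and Baf45d siRNA groups. Bars give the mean and error bars the SD of 3 libraries, and marker shapes give the replicate number. The NC libraries lie at 156.1, 154.1 and 157.5 CPM and the Baf45d libraries at 148.2, 141.4 and 147.2 CPM.

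Both groups carried neural transcripts and little of 2 pluripotency transcripts, though no untreated library is among the 6 for comparison. Matrix genes were abundant as well, with Col3a1 at 601 ± 90.9 CPM and Fn1 at 501 ± 63.8 CPM in the NC group. In the NC group the neuronal tubulin Tubb3 stood at 208.6 ± 14.4 CPM, the neural progenitor factor Sox2 at 106.6 ± 3.75 CPM, Pax6 at 14.2 ± 0.953 CPM and the intermediate filament gene Nes at 226.5 ± 46.4 CPM (SD, n = 3). The pluripotency factor Pou5f1 stood at 3.64 ± 0.552 CPM, and Zfp42, another pluripotency marker, had 0 counts in all 6 libraries. With Baf45d siRNA the levels were 235.1 ± 65.5 CPM for Tubb3, 121.0 ± 26.0 CPM for Sox2, 17.2 ± 2.24 CPM for Pax6, 207.8 ± 69.5 CPM for Nes and 3.74 ± 0.379 CPM for Pou5f1. None of these passed the threshold (edgeR adjusted p from 0.996 to 0.997). The signs for Tubb3, Nes and Pou5f1 depended on single libraries. Without Baf45d replicate 1 the log2 fold change was -0.06 for Tubb3, against 0.17 with all libraries.

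No gene differed between Baf45d and NC siRNA at an adjusted p under 0.05 in the edgeR test of 16078 genes. DESeq2 and limma-voom also called 0 genes. The 0 did not hold in edgeR without a filter on low counts, as given below. At an unadjusted p under 0.05 there were 459 genes in edgeR (195 higher and 264 lower with Baf45d siRNA) and 481 in limma-voom. Chance gives 803.9 of 16078 if the libraries are independent. DESeq2 gave 394 of the 29810 genes it tested. The groups did not overlap for 1293 genes, or 8.04%, where chance gives 10% if the libraries are independent. With the replicate number as a block, 1 gene passed and 1246 had an unadjusted p under 0.05. Simulated counts with no gene changed but with shifts shared by replicate number gave a share of 1.84% without the block and 4.61% with it. The data gave 2.85% and 7.75%. The simulated shifts had a chosen SD of 0.15 log2, so these shares are a guide only. Leaving out Baf45d replicate 3 gave 44 genes, 8 higher and 36 lower, and leaving out any other single library gave 0. The 459 genes at an unadjusted p under 0.05 became 195 without NC replicate 1, 196 without NC replicate 2, 237 without Baf45d replicate 2, 909 without Baf45d replicate 1 and 2170 without Baf45d replicate 3.

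The gene that passed with the block was Gm21887, a protein-coding gene on the X chromosome (170009659 to 170019281, plus strand, GRCm38), named after its value was seen. It stood at 56.6 ± 6.63 CPM with NC siRNA and 36.5 ± 4.12 CPM with Baf45d siRNA (SD, n = 3), and was lower in 3 of 3 pairs. Its log2 fold change was -0.64 (SE 0.12, edgeR adjusted p = 0.996) without the block and -0.63 with it (adjusted p = 0.00969). It also passed without a filter on low counts (adjusted p = 9.96e-05), and over the other alternatives its adjusted p ran from 0.0718 to 1. Its transcripts share 62% of their 31-base stretches with those of Gm47283 on the Y chromosome, so its counts are uncertain. With the block, 1 gene also passed when the libraries numbered 3 were exchanged between the groups. In simulated counts with no gene changed but shifts shared by replicate number, 2 genes passed with the block. A single call with the block is therefore no more than these comparisons gave.

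The smallest unadjusted p among genes with descriptive symbols belonged to Bcl3, Psd3, Tmem119, Foxc2 and Col6a1, all at an edgeR adjusted p of 0.996. Bcl3, an IκB-family regulator (chromosome 7, 19808462 to 19822770), stood at 12.9 ± 0.926 CPM with NC siRNA and 7.33 ± 1.62 CPM with Baf45d siRNA, a log2 fold change of -0.81 (SE 0.18). It passed without a filter on low counts (adjusted p = 0.0238) and without Baf45d replicate 3 (0.0474), and over the other alternatives its adjusted p ran from 0.118 to 1. Psd3 stood at 51.6 ± 0.369 and 67.8 ± 6.64 CPM, a log2 fold change of 0.39 (SE 0.09). Tmem119 stood at 40.6 ± 5.40 and 29.3 ± 1.48 CPM, a log2 fold change of -0.47 (SE 0.11). For these 5 genes all 3 Baf45d libraries lay on 1 side of all 3 NC libraries. Choosing genes by smallest p favours this, so it is no separate support.

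As lists, genes of the extracellular matrix and of mesoderm were lower with Baf45d siRNA in the preset test, and neither list passed with an estimated correlation or in fry. Of 25 tested members of the mesenchyme and extracellular matrix list, 22 had a negative log2 fold change, with a median of -0.19, and camera gave an adjusted p of 2.91e-05 at the preset correlation. With an estimated correlation the adjusted p was 0.397, and in fry 0.297. The collagen genes Col6a1 (23.2 ± 4.18 CPM with NC siRNA, 15.4 ± 1.57 CPM with Baf45d siRNA, log2 fold change -0.59, SE 0.15) and Col5a1 (162.1 ± 8.28 and 121.8 ± 23.8 CPM, log2 fold change -0.41, SE 0.12) had its smallest p. Col5a1 passed over all genes without a filter on low counts (adjusted p = 0.0337) and without Baf45d replicate 3 (0.0262), and its adjusted p ran from 0.0834 to 1 over the other alternatives. With all libraries and the filter, no member passed over all genes or adjusted over the list alone, and 7 passed adjusted over the list alone with the replicate block. List scores were 0.13 ± 0.02 with NC siRNA and -0.13 ± 0.18 with Baf45d siRNA (SD, n = 3; exact permutation p = 0.1).

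Of 17 tested mesoderm genes, 14 had a negative log2 fold change, with a median of -0.28 and a camera adjusted p of 1.05e-04. The adjusted p was 0.209 with an estimated correlation and 0.0923 in fry. Foxc2, a forkhead factor of paraxial mesoderm (chromosome 8, 121116171 to 121118895), stood at 12.6 ± 0.238 CPM with NC siRNA and 7.38 ± 1.83 CPM with Baf45d siRNA (log2 fold change -0.77, SE 0.19). Meox1, a somite homeobox gene, stood at 51.4 ± 9.74 and 39.1 ± 1.53 CPM (log2 fold change -0.40, SE 0.13). No member passed over all genes, 1 passed adjusted over the list alone and 3 with the replicate block. The early mesoderm genes T, Mesp1 and Msgn1 lay under the filter, with 3, 2 and 0 counts over the 6 libraries. List scores did not overlap between groups (0.15 ± 0.05 and -0.15 ± 0.03, exact permutation p = 0.1).

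Transcripts of SMAD signaling were examined because the series names that pathway. Of 25 tested SMAD target genes, 17 had a negative log2 fold change, with a median of -0.20 and a camera adjusted p of 0.00177. With an estimated correlation the adjusted p was 0.634, and without Baf45d replicate 1 the preset test gave 0.158. Bambi, a decoy receptor induced by BMP and TGF-beta signaling, stood at 45.4 ± 1.79 CPM with NC siRNA and 36.5 ± 4.76 CPM with Baf45d siRNA (log2 fold change -0.31, SE 0.11). The T-box gene Tbx3 stood at 103.1 ± 8.14 and 87.3 ± 2.87 CPM (log2 fold change -0.24, SE 0.08). No member passed over all genes or adjusted over the list alone, and 6 passed adjusted over the list alone with the replicate block. SMAD target list scores were 0.06, 0.04 and 0.20 in the NC libraries and -0.22, -0.21 and 0.14 in the Baf45d libraries, so the groups overlapped (exact permutation p = 0.3).

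The SMAD pathway components, 38 tested genes for ligands, receptors, antagonists and SMAD proteins, did not pass as a list (camera adjusted p = 0.267), with 18 higher and 20 lower. Log2 fold changes were -0.15 (SE 0.08) for Smad1, 0.10 (SE 0.09) for Smad2 and -0.07 (SE 0.09) for Smad3. For Smad4 and Smad5 they were -0.01 (SE 0.08) and -0.01 (SE 0.08), with signs that turned when single libraries were left out. The 5 genes had edgeR adjusted p from 0.996 to 0.997. Tdgf1, a co-receptor of Nodal, stood at 1.29 ± 0.463 CPM with NC siRNA and 0.625 ± 0.246 CPM with Baf45d siRNA. The BMP antagonist Nog stood at 20.5 ± 1.25 and 17.5 ± 1.11 CPM.

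The neuron list was called higher with Baf45d siRNA in the preset test only, with adjusted p of 0.922 at an estimated correlation and 0.865 in fry. Of 40 neuron genes, 34 had a positive log2 fold change, with a median of 0.18 and a camera adjusted p of 3.93e-04 at the preset correlation. The call ended without NC replicate 2 or without Baf45d replicate 1, with adjusted p up to 0.861. Gap43, a growth-cone gene, stood at 33.8 ± 2.96 CPM with NC siRNA and 40.9 ± 2.69 CPM with Baf45d siRNA (log2 fold change 0.27, SE 0.10), and Elavl2 at 41.6 ± 2.27 and 50.1 ± 6.48 CPM (log2 fold change 0.27, SE 0.11). With all libraries no member of the list passed over all genes or adjusted over the list alone. Without Baf45d replicate 3, Map2 passed over all genes (log2 fold change 0.53, adjusted p = 0.0259). Neuron list scores were -0.05, -0.19 and 0.02 in the NC libraries and 0.36, 0.10 and -0.24 in the Baf45d libraries, so the groups overlapped (exact permutation p = 0.5).

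Of 28 neural progenitor genes, 18 had a positive log2 fold change, with a median of 0.12 and a camera adjusted p of 0.0309. The adjusted p was 0.922 with an estimated correlation and 0.176 with the replicate block, and omission of NC replicate 1, NC replicate 2 or Baf45d replicate 1 raised it to as much as 0.741. Cdh2, which encodes N-cadherin, stood at 347.3 ± 17.5 CPM with NC siRNA and 403.3 ± 40.7 CPM with Baf45d siRNA (log2 fold change 0.22, SE 0.09), and Irx5 at 6.98 ± 0.815 and 9.08 ± 0.706 CPM (log2 fold change 0.38, SE 0.16). No member passed over all genes or adjusted over the list alone.

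**Figure D2:**
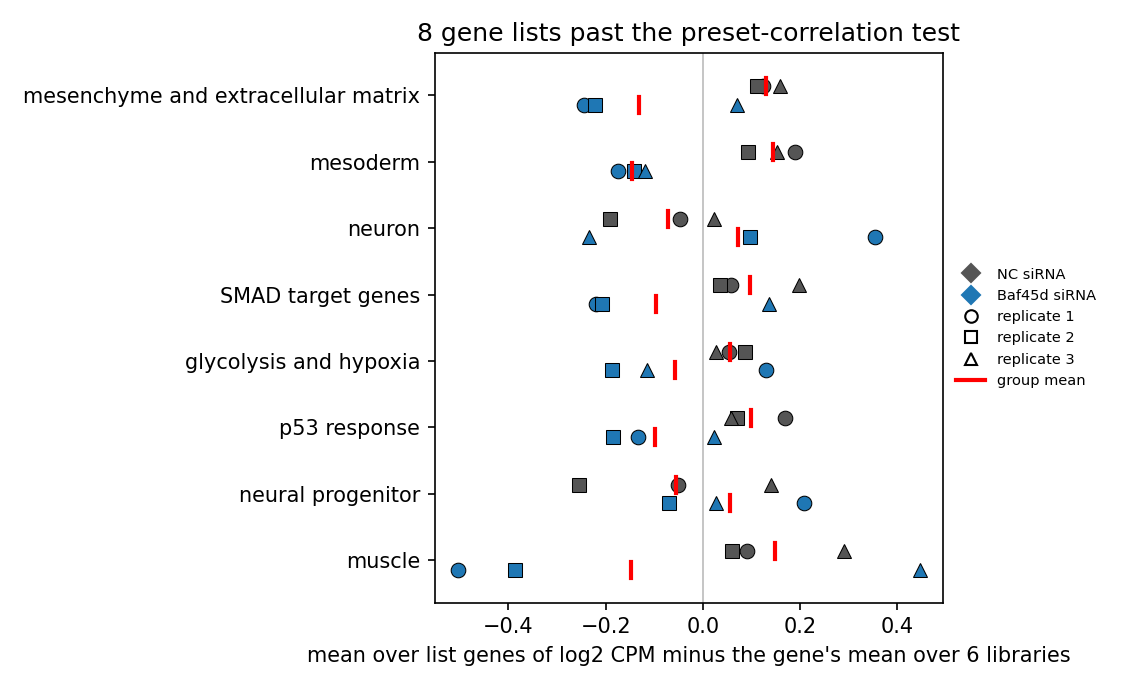
Scores of the 8 lists with a camera adjusted p under 0.05 at the preset correlation, 1 point per library. The horizontal axis is the mean over list genes of log2 CPM minus the gene's mean over 6 libraries, colours give the group, shapes the replicate number and red bars the group mean. The groups do not overlap for the mesenchyme and extracellular matrix, mesoderm and p53 response lists, and Baf45d replicate 3 lies at 0.45 in the muscle list against -0.50 and -0.39 for Baf45d replicates 1 and 2.

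The glycolysis and hypoxia list and the p53 response list were lower with Baf45d siRNA in the preset test only. With an estimated correlation their adjusted p was 0.922 and 0.516. Glycolysis and hypoxia genes had a negative log2 fold change in 20 of 23 (median -0.16, camera adjusted p = 0.00283). Their list score in Baf45d replicate 1, 0.13, lay above the 0.05, 0.09 and 0.03 of the NC libraries, 2 of 3 pairs were lower, and the exact permutation p was 0.4. Ndrg1, a hypoxia-induced gene, stood at 30.1 ± 1.66 CPM with NC siRNA and 22.1 ± 7.45 CPM with Baf45d siRNA, and the glycolytic gene Pgk1 at 686.9 ± 26.9 and 603.3 ± 86.9 CPM. The call ended without Baf45d replicate 3 (adjusted p = 0.234). Gapdh, a member with many pseudogenes, went the other way in that library, at 236.2 CPM against 14.02 to 31.17 CPM in the other 5. The labels' treatment text also names a gapdh siRNA, without assigning it to any of the 6 libraries, so what this value means is open. The p53 response list had 13 of 17 members with a negative sign (median -0.13, camera adjusted p = 0.00862; exact permutation p = 0.1 for the scores), with Phlda3, a p53-induced gene, at 12.5 ± 1.80 and 8.69 ± 1.53 CPM. Its call ended without Baf45d replicate 1 or Baf45d replicate 2 (adjusted p up to 0.158). With the replicate block, 2 p53 response genes passed adjusted over the list alone, against 0 without it.

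The muscle list had 9 of 12 members with a negative sign (median -0.16, camera adjusted p = 0.0309, and 0.922 with an estimated correlation). The contractile genes Tnni1 and Tpm2 stood at 0.901 ± 0.209 and 34.5 ± 1.60 CPM with NC siRNA and at 0.489 ± 0.143 and 29.7 ± 2.93 CPM with Baf45d siRNA. Among the 6 omissions of 1 library, the muscle call held without NC replicate 2 and without Baf45d replicate 3 and ended in the other 4, with adjusted p up to 0.613. The integrated stress response list missed the threshold (camera adjusted p = 0.0535, 15 of 22 negative) and passed with the replicate block (0.0155), where the estimated correlation gave 0.88 and 1 member passed adjusted over the list alone. It also passed without NC replicate 1 (0.0248), without NC replicate 2 (0.0118) and without Baf45d replicate 3 (3.32e-05), and stood at 0.811 without NC replicate 3. The stress genes Nupr1 and Xbp1 stood at 3.20 ± 0.320 and 78.4 ± 3.49 CPM with NC siRNA and at 1.95 ± 0.914 and 69.2 ± 4.07 CPM with Baf45d siRNA. With all libraries no member of these 2 lists passed over all genes, and without the block none passed adjusted over the list alone. Without Baf45d replicate 3, Myl9 of the muscle list (log2 fold change -0.70, adjusted p = 0.0157) and Cebpb of the stress list (log2 fold change -1.38, adjusted p = 0.0277) passed over all genes.

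The remaining lists did not pass, with camera adjusted p of 0.344 for BAF complex subunits and for cell cycle, 0.415 for endoderm, Notch and retinoic acid response, 0.614 for interferon response, neural crest and pluripotency, 0.8 for housekeeping, 0.843 for glia, 0.864 for cholesterol synthesis, 0.961 for endothelium and blood and for Hox, and 0.988 for Wnt. Leaving out 1 library called some of them. Without Baf45d replicate 3 the BAF subunit list passed as up (0.0145), Hox as up (0.0212), endoderm as down (0.0255) and cholesterol synthesis as down (0.0179). That omission leaves NC replicate 3 without its partner. Without both libraries numbered 3 the camera adjusted p of these lists was 0.0147, 0.0368, 0.0648 and 0.898. The cell cycle list passed as up without Baf45d replicate 1 (0.0118), Notch as up without NC replicate 1 (0.0259) and cholesterol synthesis as up without NC replicate 3 (0.00539). With all 6 libraries, none of the members of these lists passed over all genes or adjusted over the list alone, and with the replicate block 2 passed adjusted over the list alone in each of endoderm, neural crest, and endothelium and blood. Of 30 BAF subunit genes, 21 had a positive sign, with a median log2 fold change of 0.07, and Brd7 stood at 110.6 ± 1.96 CPM with NC siRNA and 123.2 ± 5.47 CPM with Baf45d siRNA. Of 28 Hox genes, 18 had a positive sign (median 0.02) while the test pointed down. Hoxc8 stood at 35.3 ± 1.42 and 46.9 ± 9.52 CPM and Hoxb1 at 4.97 ± 0.291 and 3.11 ± 0.864 CPM. For neural crest and for endothelium and blood the test pointed up while the median was -0.06 and -0.07. The endoderm factors Gata6 and Sox7 stood at 69.7 ± 5.21 and 9.03 ± 0.867 CPM with NC siRNA and at 56.1 ± 4.95 and 6.14 ± 0.955 CPM with Baf45d siRNA (all mean ± SD, n = 3).

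Further members of the lists did not pass either, those given here all at an edgeR adjusted p of 0.996. Log2 fold changes were -0.78 (SE 0.23) for the interferon-induced gene Oasl2 and 0.14 (SE 0.14) for Ddx58, 0.83 (SE 0.25) for the endothelial receptor Tek and -0.25 (SE 0.19) for Gata2. They were 0.38 (SE 0.12) for Ednrb and 0.38 (SE 0.16) for Tfap2b in neural crest, -0.34 (SE 0.11) for Wnt4 and 0.48 (SE 0.20) for Lgr5 in Wnt, and -0.42 (SE 0.14) for Rarg and 0.24 (SE 0.11) for Aldh1a2 in retinoic acid response. For Dll1 and Notch1 they were 0.38 (SE 0.23) and 0.24 (SE 0.17), for the cell cycle genes Top2a and Bub1 0.18 (SE 0.09) and 0.19 (SE 0.11), and for the subunit gene Bcl7b -0.22 (SE 0.11). Lefty1 had -0.38 (SE 0.19), Eda2r of the p53 list -0.97 (SE 0.52), and Olig1 -0.53 (SE 0.32). Mvd had -0.15 (SE 0.15) and Nsdhl 0.13 (SE 0.18), the latter at -0.09 without Baf45d replicate 3. Rpl13a of the housekeeping list had 0.17 (SE 0.11).

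**Figure D3:**
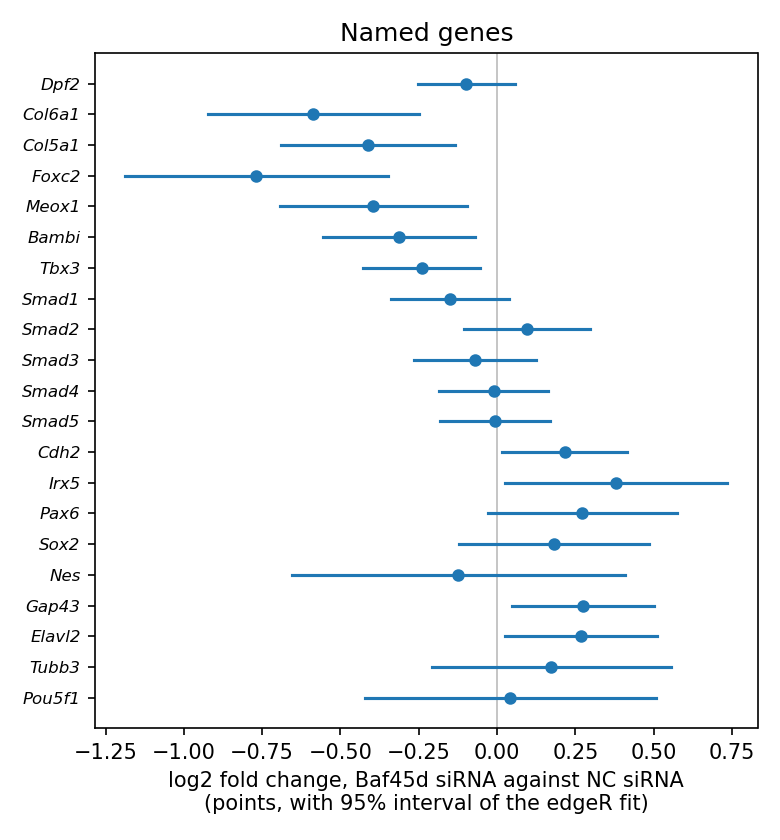
Log2 fold change of Baf45d siRNA against NC siRNA (horizontal axis) for 21 named genes, with the 95% interval of the edgeR fit. None of them passed after adjustment. Dpf2 lies at -0.10 and Foxc2 at -0.77.

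The authors' deposited table gave a p-value for 27064 genes, of which 394 had an unadjusted p under 0.05 and 0 an adjusted p under 0.05, with a smallest adjusted p of 0.0652. It gave Dpf2 a log2 fold change of -0.10 (unadjusted p = 0.278). All 179 genes counted in the authors' deposited term tables had an unadjusted p under 0.05 in the authors' deposited gene table, 64 of them up and 115 down. These genes were chosen on the same libraries, so the terms are not independent evidence of direction.

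The authors' deposited Reactome table listed extracellular matrix organization first, with 18 genes, 2 up and 16 down (adjusted p = 7.89e-04), and gave collagen formation 9 genes, all down (adjusted p = 0.00515). It also held TGF-beta receptor signaling activates SMADs with 4 genes, 1 up and 3 down (adjusted p = 0.0386), and axon guidance with 14 genes, 6 up and 8 down (adjusted p = 0.0394). In the authors' deposited KEGG table, signaling pathways regulating pluripotency had 10 genes, 1 up and 9 down (adjusted p = 0.0362), among them Tbx3, Id3, Stat3, Fzd7 and Wnt4. Oxidative phosphorylation had 10 genes, 6 up and 4 down (adjusted p = 0.0362), of which 5 are mitochondrially encoded.

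Mitochondrially encoded transcripts varied mostly in 1 library. They made up 2.54% of counts in Baf45d replicate 2 and 1.52% to 1.85% in the other 5 libraries. Group means were 1.59 ± 0.0719% with NC siRNA and 1.97 ± 0.52% with Baf45d siRNA (SD, n = 3; exact permutation p = 0.4). Over 12 mitochondrially encoded protein genes the mean log2 fold change in edgeR was 0.27 with all libraries, 0.11 without Baf45d replicate 2 and 0.43 without Baf45d replicate 1. None of the 12 passed, and 2 had an unadjusted p under 0.05 with all libraries, 7 without Baf45d replicate 1, 2 without NC replicate 3 and 0 without any other single library. Ndufa12, counted as down in the authors' oxidative phosphorylation term, stood at 33.5 CPM in NC replicate 1 and from 10.5 to 16.1 CPM in the other 5 libraries.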

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

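The settings without both libraries numbered 3, without mitochondrially encoded genes, and with the replicate block in camera at an estimated correlation or in fry were chosen after seeing the data. Of 21 alternatives for the count of genes, 17 gave 0 as the main comparison did, among them both other scalings, the filter at 5 CPM, DESeq2, limma-voom, all 3 fits on FPKM and both stricter thresholds. The 0 of both stricter thresholds was fixed by the 0 of the main comparison, so these add no support. Without a filter on low counts 10 genes passed, 2 higher and 8 lower, and 1147 of 29811 had an unadjusted p under 0.05. All 10 were also tested with the filter, and their total counts ran from 1121 (Bcl3) to 68121 (Igfbp3). With the filter the smallest edgeR adjusted p was 0.996, so the 0 of the main comparison depends on the filter. At an unadjusted p under 0.05, limma on log2(FPKM + 1) with no filter gave 964 of 29811. With the replicate block 1 gene passed, 0 higher and 1 lower, and 1246 had an unadjusted p under 0.05. Beyond this gene and the list calls in the report, the block changed no other call. Leaving out each library in turn gave 0 to 44 genes, 0 to 8 higher and 0 to 36 lower, 195 to 2170 genes at an unadjusted p under 0.05, and 4 to 12 lists. The high ends came without Baf45d replicate 3, and the 4 lists without Baf45d replicate 1. Without both libraries numbered 3 there were 20 genes, 2 higher and 18 lower, 1715 at an unadjusted p under 0.05, and 10 lists. Without mitochondrially encoded genes the counts were 0 genes, 457 at an unadjusted p under 0.05 and 8 lists.

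The 8 lists of the preset test became 0 with an estimated correlation and 0 in fry. With the replicate block each also gave 0. The block leaves still fewer residual degrees of freedom for these tests, so that 0 is no separate support. Among these 8 lists the estimated correlation among members was highest in the neuron list, at 0.59 without the block and 0.8 with it. A list with correlated members carries fewer independent genes than the preset value assumes. This does not account for the mesoderm list, whose estimated correlation without the block was -0.032. Its unadjusted camera p still rose from 8.78e-06 at the preset to 0.00872 at the estimated correlation. At an estimated correlation camera judges its statistic on the few residual degrees of freedom of the libraries, and at the preset on the number of genes. This difference applies to all 8 lists, so the loss of their calls need not reflect correlated members. The Hox list turned to up without Baf45d replicate 3 (adjusted p = 0.0212, the lowest of the 6 omissions, where the highest was 0.971) and without both libraries numbered 3 (0.0368). The cholesterol synthesis list turned to down without Baf45d replicate 3 (0.0179) and passed as up without NC replicate 3 (0.00539), with 0.544 the highest of the 6 omissions. All 20 tested members were higher in both libraries numbered 3 than in the others, so each of these omissions left 1 such library unbalanced. Without both libraries numbered 3 the adjusted p was 0.898, so these 2 calls are no evidence of an siRNA effect. Where no cause is named, the cause was not tested. Dpf2 kept its negative sign in all 19 alternatives and passed in none, with log2 fold changes from -0.11 to -0.07. Over 62 named genes, 1140 of 1155 alternatives kept the sign, 56 genes kept it throughout, and 6 alternatives passed the threshold. Scaling moved the median log2 fold change of all genes only from -0.0086 to 0.0074. In simulated counts of this design, 48.5% of genes changed 1.5-fold were found without a block. These counts lacked shifts shared by replicate number, so the rate need not hold for the data.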

Other observations

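The 3 tests on Dpf2, the single-library tests on parts of the list calls, and the values of libraries numbered 3 and single genes given here were chosen only after the result was seen. Cholesterol synthesis genes stood apart in both libraries numbered 3, whichever siRNA was used. All 20 tested members were higher in NC replicate 3 and Baf45d replicate 3 than in each of the other 4 libraries, where 17.1% of all 16078 tested genes were and unrelated libraries give 6.67%. Insig1 stood at 102.0 and 110.0 CPM in these 2 libraries and from 57.6 to 62.2 CPM in the others, and Sqle, an enzyme of sterol synthesis, at 176.7 and 175.2 CPM against 117.2 to 123.9 CPM. Integrated stress response genes went the same way in 17 of 22.

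In the same 2 libraries, 11 of 28 Hox genes and 10 of 22 retinoic acid response genes were lower than in each of the other 4, where 15.4% of all tested genes were. The first principal component, 38.6% of the variance, placed NC replicate 3 at 21.8 and Baf45d replicate 3 at 27.4, and Baf45d replicates 1 and 2 at -20.4 and -28.2. NC replicates 1 and 2 lay between, at -1.51 and 0.854. Rpl37, a ribosomal protein gene, stood at 467.2 CPM in Baf45d replicate 2 and from 269.7 to 281.9 CPM elsewhere.

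The Dpf2 transcript was close to control in the Baf45d siRNA libraries. Libraries swapped between groups, or 1 wrong label, would leave a library with a low transcript among the 6 only if the transcript was lowered at harvest. The lowest held 89.8% of the highest. Without a lowered transcript at harvest, this value cannot decide whether the labels are right. Too little depth or replication is argued against by the interval of the log2 fold change, whose lower bound was -0.25. A knockdown that had faded by the harvest on day 5 may remain, since the value of -0.10 comes from 1 time point. Equally, the transcript may have stood near the control level at earlier times too, with no appreciable knockdown. Loss of the protein without loss of the transcript was not measured. These cannot be told apart here.

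Fewer genes had an unadjusted p under 0.05 without a block (459, or 2.85%) than chance gives for independent libraries. Discrete low counts are argued against, since the share was 2.6% among genes at 5 CPM or more. Differences shared by libraries of the same number are consistent with the data. Among the 6 ways to pair the libraries, the labelled one ranked 1 by genes at an unadjusted p under 0.05, with 1246 against at most 841 for the other 5. This rank rests on the same correlations by which the pairing was adopted, so it is not separate support. One library standing apart is also consistent, since without Baf45d replicate 3 the share rose to 13.3%, and without Baf45d replicate 1 to 5.54%. These explanations overlap, and no biological one was tested.

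Camera at the preset correlation called lower extracellular matrix, mesoderm and SMAD target lists and a higher neuron list. All 4 calls were lost with an estimated correlation (adjusted p = 0.397, 0.209, 0.634 and 0.922) and in fry (0.297, 0.0923, 0.345 and 0.865). For a single library, the test written beforehand on all 4 lists was undecided, since 1 omission ended at most 2 of the 4 calls. By parts, a single library is argued against for the extracellular matrix and mesoderm lists, since 0 of the 6 omissions ended both calls and neither call ended in any. For the SMAD target and neuron lists it may contribute, since 1 omission, of Baf45d replicate 1, ended both. Differences between cultures in how far differentiation went, unrelated to the siRNA, stay open. The SD within groups exceeded the difference between groups for 1 of the 4 lists (neuron), and the groups did not overlap for the extracellular matrix and mesoderm lists, but 3 of 24 lists did not overlap where chance gives 2.4, so that bound excludes nothing. These values do not use the pairing. By pairs, scores were lower with Baf45d siRNA in 3 of 3 for the extracellular matrix, mesoderm and SMAD target lists and in 1 of 3 for the neuron list, though the scores of the SMAD target and neuron lists overlapped between groups. These are too few pairs to settle it. An effect of the siRNA stays open as well.

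With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 0 genes past the adjusted threshold, as did 10 of 10 splits, and the highest other was 0. At an unadjusted p under 0.05 it gave 459 genes, 7 of 10 splits gave as many, and the highest other was 2342, for NC replicate 1 with Baf45d replicates 1 and 2. That count, several times larger, points to a structure of the samples. This split sets 2 of 3 Baf45d libraries against 2 of 3 NC libraries, with both libraries numbered 3 on the same side. Every split but the real one has such a 2 to 1 makeup, and the lowest count among them was 109. The real split holds the full siRNA contrast and gave fewer genes, which argues against the siRNA alone as the source of the 2342. For lists, the real split gave 8, 5 of 10 gave as many, and the highest other was 12. Of the 4 splits that part all 3 pairs, the real one gave 1246 genes at an unadjusted p under 0.05 and 8 lists with the block. The split that exchanges the libraries numbered 3 gave 1475 and 12, and the remaining 2 gave 128 and 598 genes and 0 and 3 lists.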
